A study of Mus musculus with 15 samples.

How the data were processed

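The samples were 15 arrays of pooled mouse liver in 5 groups of 3 pools: control, IUGR F1 (underfed before birth), ON F1 (overfed during lactation), and IUGR F2 and ON F2 (male offspring of those males). Groups were taken from the sample titles and treatment labels, which number the pools 1 to 15 and give no pairing between pools. None was modelled. Whether an F2 pool holds sons of the males in a given F1 pool is not stated. Per the labels, livers were frozen in liquid nitrogen, RNA was extracted with Trizol, and 2 ug of total RNA was amplified, biotin-labelled and hybridised to the Affymetrix GeneChip Mouse Genome 430 2.0 array. Nothing in the labels says whether the pools of a group hold separate litters, so p-values measure the spread between these pools. Pooling averages over animals, so the spread between single mice is unknown.

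The deposited values are log2 expression levels per probe set, which the authors made with RMA per the submitters' processing notes. RMA corrects background, normalises the arrays to each other by quantiles and summarises the probes of a set. Its version is not given in the sources used here. The log2 scale was read from the values, whose array medians lay between 4.60 and 4.68. Quantile normalisation removes shifts shared by most genes of an array, and summaries of dim probe sets are compressed towards background, so changes of dim genes are understated. The number of arrays limits the precision. The median standard error of a difference was 0.104, and 7830 of 18193 genes had a mean below 5. The ratio of 3' to 5' actin control probe sets, a sign of RNA length, was 1.76 to 2.28 on the log2 scale, and that of Gapdh control probe sets 1.08 to 1.45. Actin averaged 1.87 in control, 1.88 in IUGR F1, 2.08 in ON F1, 2.02 in IUGR F2 and 2.04 in ON F2 pools, and Gapdh 1.15, 1.14, 1.29, 1.28 and 1.16 in the same order. Pools 12 and 8 stood highest (actin 2.28 and 2.22, Gapdh 1.45 and 1.43). This ratio was not a covariate in any fit.

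The array holds 45101 probe sets, of which 64 controls were left out. Of the remaining 45037, 34945 were annotated with 1 gene symbol, 932 with several and 9160 with none, and probe sets with several symbols or none named no gene. Through Entrez identifiers 34741 matched the GRCm38.p6 RefSeq gene table, and 0 symbols changed. Each of 18193 genes was read at the probe set with the highest mean over all 15 arrays, where 9010 genes had more than 1. Some genes of interest to this tissue were not analysed here.

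Differences were tested in R 4.3.3 with limma 3.58.1: 1 linear model with 5 group means over all 15 arrays, empirical Bayes moderation without a trend, two-sided tests and Benjamini-Hochberg adjustment over all genes within a comparison, at an adjusted p of 0.05. The prior had 4.69 degrees of freedom beside 10 residual ones. The comparisons were each of the 4 groups against control, F2 against F1 within each lineage, IUGR against ON within each generation, the difference of those differences (lineage by generation interaction), and an F test over all groups. No filter on dim genes was applied. On 20 simulated data sets for IUGR F2 against control with 18193 genes, 66.5% of 67 genes changed by 0.5 log2 were recovered, 97.3% of 67 changed by 1 and 99.8% of 66 changed by 2, with a mean of 8.7 false calls and 0 calls of the wrong sign. Genes were drawn there as independent and normal, and the many large planted changes ease the adjustment over all genes. These shares therefore do not give the recovery in the real data. There, Ighm at -2.14 ± 0.50 was not called in the same comparison (limma adjusted p = 0.438).

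The groups, tests, gene lists, named genes and most alternatives were chosen before the data were examined. The 43 fixed lists, 14 of them cell type or tissue markers, hold 961 entries, of which 845 were measured, 16 of them through an older symbol. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, adjusted over the 43 lists, and its members also over the list alone. A panel of 31 metabolic and epigenetic genes was fixed as well. Of it 26 were measured and 5 were not analysed here. Named genes followed a rule. Against control, these were the 10 called genes that rose most and the 10 that fell most, with all 3 pools outside the range of the other group. Where fewer than 5 of a direction passed, the 5 with the smallest p were taken instead. Called list members were added, at most 4 per list, or, where none passed, up to 2 with the smallest p for lists that passed camera. The panel completed the rule. Comparisons without control arrays named 5 genes per direction, and the further called list members printed for ON F2 against ON F1 were chosen after their values were seen. List members named because they passed over the list alone, the T cell genes and the pools singled out were chosen after their values were seen.

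Recurrence across generations was measured as the Pearson correlation across genes of 2 sets of fold changes against control. Both share the control pools, so 1000 sets of 2 unchanged groups and a shared control were simulated. Each was drawn from the residual arrays, which hold the difference of every pool from its group mean, shuffled and with random signs, so that the correlation between genes was kept. The overlap at an unadjusted p was simulated the same way in 100 full refits. A correlation that shares no array was computed from IUGR minus ON in each generation and compared with all 100 relabellings of the pools. With 3 pools against 3 there are 10 splits and an exact test cannot go below 0.1, so single values were tested in the model only. A clock score per pool was the first principal component of 22 circadian genes, which held 84.4% of their variance.

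Alternatives were every probe set on its own, the mean of a gene's probe sets, no cross-hybridising probe sets, only genes above the median level, renewed quantile normalisation, trended robust moderation, array weights, only the 6 arrays compared, rank correlation, and each pool left out. The clock score as a covariate and the removal of pools 5, 8 and 13 together were added after the data were seen.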

Results

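Gene expression was measured in whole liver of adult male mice on the Affymetrix GeneChip Mouse Genome 430 2.0 array, an oligonucleotide array that reads most mouse genes through 1 or more probe sets. The study asked whether expression patterns of males that met a perinatal nutritional challenge are found again in the sons they fathered. Each of the 15 arrays held a pool of liver samples, and each of the 5 groups had 3 pools. The number 3 in the sample titles is read here as livers per pool. IUGR F1 pools came from males underfed by 50% before birth, and ON F1 pools from males overfed while suckling. IUGR F2 and ON F2 pools came from the male offspring of those males. The control pools drew on both generations together, so neither generation had control arrays of its own, although the design text lists a control group for each. Values are log2 RMA (robust multi-array average) levels with SD over 3 pools, and differences are log2 fold changes with the standard error from limma.

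The labels and the arrays were compared first. In each of the 15 pools the X-inactivation transcript Xist stood between 3.75 and 4.44 and the Y-linked gene Eif2s3y between 7.59 and 8.22, as in male tissue. Pairwise correlations between arrays, across probe sets, lay between 0.9837 and 0.996. They averaged 0.9938 within groups and 0.9925 between groups, and 0 pairs of arrays held identical values. The 3 pools of a group differed in the clock gene Dbp, which peaks once a day in liver and ranged from 5.30 to 10.71. Dbp stood above 9 in control pool 2, IUGR F1 pools 5 and 6 and ON F2 pools 13 and 14, and between 5.34 and 6.23 in the ON F1 pools. Genes of the exocrine pancreas were high in ON F2 pool 13, interferon response genes in ON F1 pool 8 and skeletal muscle genes in IUGR F1 pool 5. The list medians of these pools stood 4.25, 0.99 and 0.52 above the mean of the control pools. A moderated F test over the 5 groups called 34 of 18193 genes at an adjusted p under 0.05, 7 without IUGR F1 pool 6 and 9 with the clock score as a covariate.

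**Figure D1:**
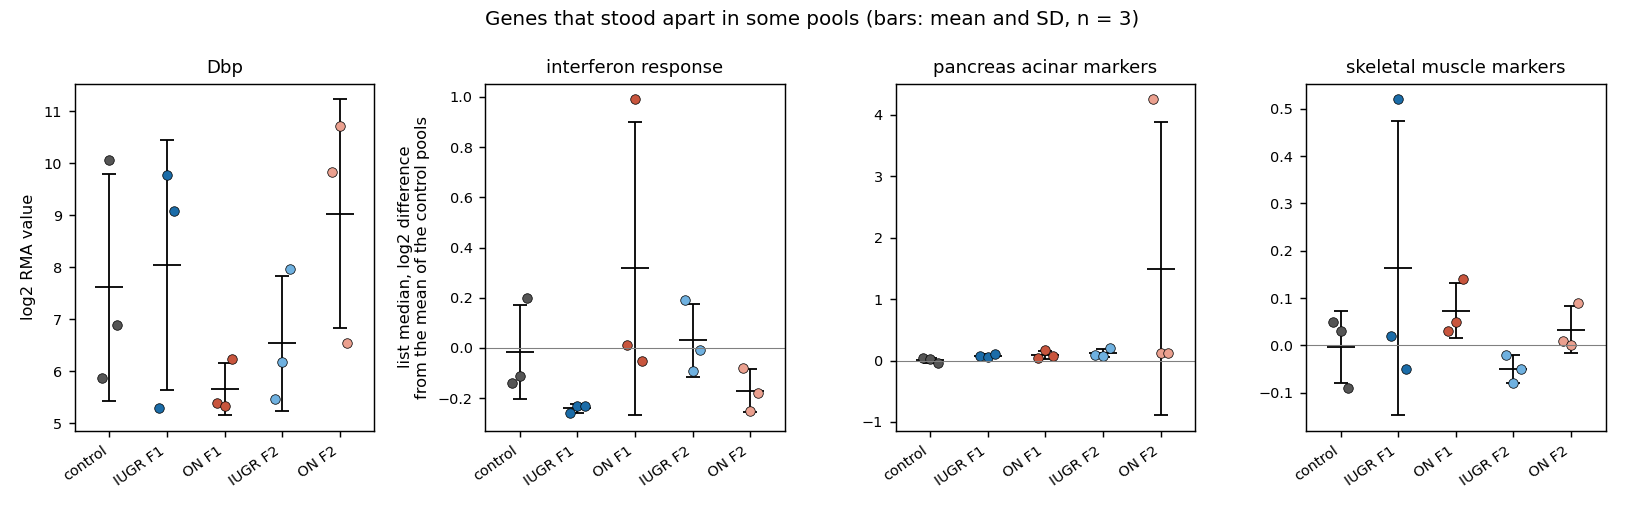
Each point is 1 pool, and bars give the mean and SD of the 3 pools of a group. The first panel shows the log2 RMA value of Dbp and the other panels the median of a gene list as a log2 difference from the mean of the control pools, with ON F1 pool 8 at 0.99 for interferon genes, ON F2 pool 13 at 4.25 for pancreas genes and IUGR F1 pool 5 at 0.52 for muscle genes.

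In livers of males underfed before birth, markers of Kupffer cells, the resident macrophages of the liver, lay lower than in control livers. All 19 measured members were negative, with a median difference of -0.48. The shift of the list did not hold in camera with an estimated correlation between genes (adjusted p = 0.911). The complement genes C1qa and C1qb, which these macrophages express strongly, stood at 7.44 ± 0.10 and 6.52 ± 0.03 in IUGR F1 and at 7.96 ± 0.37 and 7.16 ± 0.47 in control pools. Interferon response genes (22 of 25 negative, median -0.27), acute phase genes (22 of 23, median -0.30) and unfolded protein response genes (22 of 24, median -0.15) also lay lower. So did cholesterol synthesis genes (15 of 19, median -0.21), heat shock genes (14 of 17, median -0.13) and NRF2 antioxidant genes (16 of 18, median -0.09). In pools 4, 5 and 6 the acute phase median was -0.27, 0.00 and -0.61. The unfolded protein response stood at -0.08, 0.10 and -0.39 and heat shock genes at -0.21, 0.17 and -0.42. Other splits of these and the control pools reached 0.44, 0.24 and 0.36 in size, in that order. They reached 0.28 for cholesterol synthesis, 0.20 for NRF2 genes, 0.20 for interferon genes and 0.35 for Kupffer cell markers. These last lists were negative in each IUGR F1 pool.

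The members of these groups with the smallest p were each short of the threshold. Among the interferon genes, the chemokine Cxcl10 differed by -0.50 ± 0.17 and the signal transducer Stat2 by -0.25 ± 0.10. The acute phase proteins Crp and Apcs differed by -0.38 ± 0.13 and -0.60 ± 0.23. The endoplasmic reticulum chaperone Hsp90b1 differed by -0.34 ± 0.11 and asparagine synthetase, Asns, by -0.66 ± 0.34. Of the cholesterol enzymes, Dhcr7 differed by -0.32 ± 0.15 and Hmgcs1 by -0.40 ± 0.22. The cytosolic chaperones Dnajb1 and Hsp90aa1 differed by -0.42 ± 0.17 and -0.39 ± 0.19, and the antioxidant genes Nqo1 and Hmox1 by -0.35 ± 0.12 and -0.41 ± 0.18. Skeletal muscle genes lay higher (10 of 12 positive, median 0.14), with Myl1 at 0.58 ± 0.22 and Myh1 at 0.25 ± 0.11. Their list median stood at 0.52 in pool 5 and at 0.02 and -0.05 in pools 4 and 6.

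The enzymes of fat synthesis lay near control levels in IUGR F1. Fasn, the fatty acid synthase, differed by -0.10 ± 0.31, Acaca by -0.09 ± 0.22, Scd1 by -0.02 ± 0.14 and their regulator Srebf1 by 0.11 ± 0.25. G6pc, which releases glucose from the liver, differed by 0.55 ± 0.16 (adjusted p = 0.432). The insulin pathway genes Insr, Irs1 and Irs2 differed by -0.19 ± 0.09, 0.02 ± 0.08 and 0.40 ± 0.27, Igf1 by 0.07 ± 0.12 and the DNA methyltransferases Dnmt1 and Dnmt3b by -0.15 ± 0.10 and 0.38 ± 0.21.

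Limma called 0 of 18193 genes between IUGR F1 and control at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1534, of which 994 were higher and 540 lower, where chance alone gives 910. The smallest adjusted p on the lower side was 0.0829, for the interferon-inducible gene Mndal (-0.73 ± 0.10), followed by Tpsg1 (-0.60 ± 0.11), Lpxn, Emilin2 and C1galt1. On the higher side it was 0.0942, for the amino acid transporter family member Slc7a4 (0.51 ± 0.08), followed by Rimklb (0.40 ± 0.07), the DNA sensor Cgas (0.52 ± 0.09), Adm2 and D6Ertd474e. With limma's camera at a preset correlation between genes, 8 of 43 lists passed at an adjusted p under 0.05. The adjusted p was 2.42e-08 for the Kupffer cell list, 0.000865 for interferon and acute phase genes, 0.00137 for cholesterol synthesis and 0.00143 for the unfolded protein response. It was 0.00564 for heat shock genes and 0.0284 for the NRF2 and muscle lists. None of the 8 held with an estimated correlation (adjusted p = 0.911 with an estimated correlation for each), and 0 members of the 8 lists passed when adjusted over the list alone. Limma's fry, which asks whether a list moves one way, passed 0 of 43 lists. Without control pool 3, whose Kupffer median stood 0.33 above the control mean, 3 lists passed camera.

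In livers of males overfed during lactation, some sex-dependent genes stood apart from control levels. Genes that are usually higher in male liver lay lower (12 of 15 negative, median -0.23), and genes that are usually higher in female liver lay higher (11 of 15 positive, median 0.25). The male-biased gene Moxd1 stood at 6.32 ± 2.00 against 9.93 ± 0.59 in control pools. The female-biased cytochrome Cyp2b9 stood at 7.72 ± 0.92 against 5.58 ± 0.63. Other members did not follow. The male-biased genes Cyp4a12a, Cyp2d9 and Slco1a1 differed by 0.01, 0.14 and 0.03, and the female-biased genes Cux2 and Sult1e1 by 0.01 and -1.15. Adjusted over the list alone, Moxd1 fell, and Cyp2b9, Cyp2b13, Fmo1, Abcd2 and Prom1 rose, although none of these 6 passed over all genes. The 3 pools were not alike in this: the male-biased list median was -0.36, -0.22 and -0.05 in pools 7, 8 and 9. Other splits of the same ON F1 and control pools gave list medians of up to 0.21 (male-biased) and 0.24 (female-biased) in size.

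Acute phase genes (22 of 23 negative, median -0.36) and cholesterol synthesis genes (19 of 19 negative, median -0.27) also lay lower in ON F1, with the plasma protein Orm2 at -2.18 ± 0.98, Crp at -0.30 ± 0.13 and the sterol enzymes Msmo1 and Nsdhl at -0.63 ± 0.25 and -0.36 ± 0.15. Unfolded protein response genes (20 of 24 negative, median -0.19) included Asns at -1.05 ± 0.34 and Hsp90b1 at -0.35 ± 0.11. Glucocorticoid response genes (11 of 15 negative, median -0.24) included the metallothionein Mt2 at -3.24 ± 1.44 and the clock gene Per1 at -0.90 ± 0.33. Heat shock genes (12 of 17 negative, median -0.22) included Hspb8 at -0.48 ± 0.14 and Hspa8 at -0.36 ± 0.19. Cytosolic ribosomal protein genes lay lower by a small amount (33 of 40 negative, median -0.08), among them Rps10 at -0.19 ± 0.07 and Rplp0 at -0.21 ± 0.08. That list also took in the mitochondrial ribosomal protein gene Mrpl23 (0.12 ± 0.10). The insulin signalling list had a median of -0.11 with 12 of 17 negative. Within it the kinase Akt1 (-0.40 ± 0.11) fell when adjusted over the list alone, and Socs3 stood at -0.63 ± 0.31. The ON F1 pools were not alike. In pools 7, 8 and 9 the median was -0.61, -0.14 and -0.08 for acute phase genes. It was -0.42, -0.11 and -0.03 for the unfolded protein response and -0.18, -0.58 and -0.13 for cholesterol synthesis. Other splits of these and the control pools reached 0.36, 0.23 and 0.35 in size, in that order. They reached 0.16 for glucocorticoid and 0.13 for heat shock genes.

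Markers of bile duct cells, the cholangiocytes, lay higher in ON F1 (10 of 12 positive, median 0.23), with the duct transcription factor Sox9 at 0.50 ± 0.17 and Pkhd1 at 0.76 ± 0.25. Most of the list was dim, with means below 5 over all 15 pools for Krt7, Krt19, Epcam, Cftr, Krt23, Cldn4, Cldn7 and Muc1. Of the brighter members, Onecut1 (-0.32 ± 0.47) and Slc4a2 (-0.28 ± 0.12) lay lower. Interferon response genes had a median of 0.47 with 19 of 25 positive, including Oasl1 at 0.68 ± 0.21 and Ifit2 at 0.48 ± 0.16. That median rested on pool 8 and was -0.06 without it. The gluconeogenic enzyme Pck1 differed by -1.42 ± 0.38 (adjusted p = 0.163), G6pc by 0.70 ± 0.16 (adjusted p = 0.111), the fatty acid transporter Cd36 by 0.78 ± 0.23 and the mitochondrial gate of fat oxidation, Cpt1a, by -0.40 ± 0.15. Igfbp2 differed by -0.59 ± 0.20. Fasn, Scd1 and Srebf1 differed by -0.02 ± 0.31, 0.01 ± 0.14 and 0.16 ± 0.25, and Insr, Irs1 and Irs2 by -0.19 ± 0.09, 0.06 ± 0.08 and 0.13 ± 0.27.

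In ON F1, 4 genes rose and 0 fell at an adjusted p under 0.05 in limma, with 2547 genes at an unadjusted p under 0.05 (1632 higher, 915 lower). Rimklb, a ligase that joins glutamate to other amino acids, rose by 0.58 ± 0.07 (adjusted p = 0.0102), and Rasl12 by 0.58 ± 0.08 (adjusted p = 0.0398). Arhgef16 and Slc7a4 rose by 0.88 ± 0.13 and 0.51 ± 0.08 (adjusted p = 0.0472 for both). With the mean of a gene's probe sets Rimklb stood at 0.26 and Slc7a4 at 0.25, neither past the threshold. The count was 0 without control pool 3 and with the clock score as a covariate, and 21 without ON F1 pool 9. Just short of the threshold were the class II antigen gene H2-Ea (0.78 ± 0.13, adjusted p = 0.0631), complement Hc (-0.65 ± 0.11, adjusted p = 0.0631) and lipoprotein lipase, Lpl (-1.29 ± 0.24, adjusted p = 0.0766), with H2bc21, Gria3 and Pitpnm2 next on the lower side. Camera passed 11 of 43 lists at the preset correlation. Adjusted p was 4.21e-05 for cholesterol synthesis and acute phase genes, 0.000462 for ribosomal proteins, 0.000543 for male-biased genes, 0.00107 for the unfolded protein response and 0.0142 for cholangiocyte markers. It was 0.0146 for the female-biased, heat shock and interferon lists, 0.0193 for glucocorticoid genes and 0.0467 for insulin signalling. None held with an estimated correlation, the lowest being adjusted p = 0.353 with an estimated correlation, for the male-biased and cholangiocyte lists. Without ON F1 pool 8, 6 lists passed camera. Limma's fry passed the cholangiocyte list alone (adjusted p = 0.00515).

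In the sons of IUGR males, genes of fatty acid synthesis lay lower than in control livers, as a group and in each pool. Of 23 measured members of the de novo lipogenesis list 22 were negative, the median was -0.40, and the medians of pools 10, 11 and 12 were -0.24, -0.50 and -0.59. Control pools 1, 2 and 3 stood at 0.13, 0.04 and -0.18, and ON F1 pool 8 at -0.25. The shift of the list did not hold in camera with an estimated correlation between genes (adjusted p = 0.485). Fasn stood at 11.07 ± 0.31 against 11.91 ± 0.32 in control pools, a difference of -0.84 ± 0.31. The desaturase genes Scd2 and Scd1 differed by -1.01 ± 0.23 and -0.41 ± 0.14, Acaca by -0.49 ± 0.22, Elovl6 by -0.73 ± 0.39 and Srebf1 by -0.43 ± 0.25. Scd2 and the citrate carrier Slc25a1 (-0.35 ± 0.10) fell when adjusted over the list alone, and 11 members had an unadjusted p under 0.05.

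**Figure D2:**
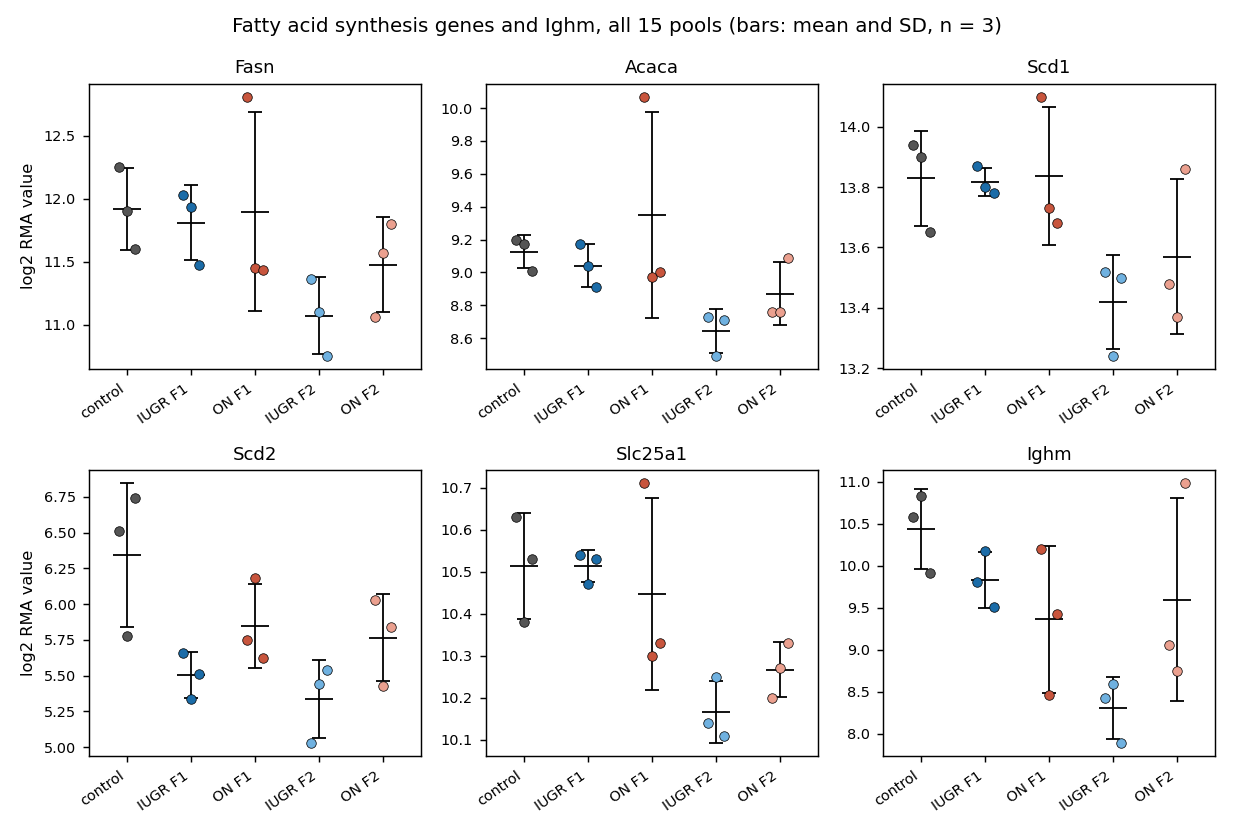
Log2 RMA values of 5 fatty acid synthesis genes and of the immunoglobulin gene Ighm in each pool, with bars for the mean and SD of the 3 pools of a group. Fasn averaged 11.07 in IUGR F2 and 11.91 in control pools, and Ighm 8.30 and 10.44.

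Neighbouring lists also lay lower in IUGR F2. LXR genes and targets, which respond to oxysterols, had a median of -0.15 with 14 of 16 negative. This list shares Fasn and Scd1 with the lipogenesis list. Its phospholipid transfer protein Pltp stood at -1.64 ± 0.54, with an SD of 1.26 in control pools. The LXR targets Abca1, Abcg8 and Apoe differed by only -0.01, -0.02 and -0.01, and Cyp7a1 by 0.34 ± 0.22. Glycolysis genes had a median of -0.14 with 8 of 9 negative. Of these Pfkl (-0.47 ± 0.11) fell when adjusted over the list alone, though another of its probe sets pointed the opposite way, and pyruvate kinase, Pklr, stood at -0.68 ± 0.30. In the lipid droplet list (15 of 18 negative, median -0.10) Pparg (-0.77 ± 0.22) and Fitm1 (-0.98 ± 0.28) fell when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.19 with 17 of 19 negative, including Nsdhl and Dhcr7 at -0.40 ± 0.15 each, and NRF2 genes a median of -0.19 with 14 of 18 negative, including Abcc4 at -0.33 ± 0.12 and Nqo1 at -0.34 ± 0.12. The fasting hormone Fgf21 differed by -0.61 ± 0.28, G6pc by 0.48 ± 0.16, Pck1 by 0.37 ± 0.38, Cpt1a by 0.10 ± 0.15 and Dnmt3b by 0.59 ± 0.21.

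Markers of some other liver cells lay lower in the IUGR F2 group, though not in each pool. Cholangiocyte, erythroid and adipocyte markers had medians of 0.07, -0.02 and -0.01. In the lymphocyte list the immunoglobulin genes Ighm (-2.14 ± 0.50) and Jchain (-1.68 ± 0.32) and the antigen presentation genes H2-Eb1, H2-Ab1 and Cd74 (-1.08, -0.51 and -0.47) fell when adjusted over the list alone, with 12 of 19 members negative and a median of -0.09. The T cell genes Cd3e and Cd4 stood at 0.03 each. Stellate cell and fibrosis genes had a median of -0.22 with 17 of 21 negative, including the collagen Col3a1 at -0.65 ± 0.21 and Lum at -0.54 ± 0.18. Kupffer cell markers had a median of -0.24 with 15 of 19 negative, including Lyz2 at -0.47 ± 0.21 and Cd14 at -0.98 ± 0.56. Sinusoidal endothelial markers had a median of -0.15 with 15 of 16 negative, including Dnase1l3 at -0.35 ± 0.16 and Cdh5 at -0.20 ± 0.12. In pools 10, 11 and 12 the Kupffer median was -0.53, 0.09 and -0.34. The endothelial median was -0.28, 0.05 and -0.26 and the stellate median -0.37, -0.09 and -0.10. Other splits of these and the control pools reached 0.42, 0.26 and 0.25 in size, in that order.

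Limma called 0 of 18193 genes between IUGR F2 and control, with 1283 at an unadjusted p under 0.05 (456 higher, 827 lower) and a smallest adjusted p of 0.259. The genes with the smallest p were Rnf144b (0.47 ± 0.08), Crym (1.09 ± 0.19), Adi1 (0.58 ± 0.11), A530053G22Rik and Plch1 on the higher side. On the lower side they were Hsd3b3 (-0.50 ± 0.09), Btrc (-0.51 ± 0.09, with 1 of 5 probe sets opposite), Igkv8-30 (-1.54 ± 0.28), Jchain and Nudt19. Camera at the preset correlation passed 10 of 43 lists. The adjusted p was 1.54e-09 for lipogenesis, 0.00239 for cholesterol synthesis, 0.00452 for the stellate cell and lymphocyte lists and 0.00645 for the Kupffer and endothelial lists. It was 0.0124 for NRF2 genes, 0.0132 for LXR genes, 0.0133 for glycolysis and 0.0235 for lipid droplet genes. None held with an estimated correlation (adjusted p = 0.485 for lipogenesis, LXR, glycolysis, stellate and lymphocyte lists and 0.721 for the rest, each with an estimated correlation). Fry passed 0 of 43 lists. Without IUGR F2 pool 10, 6 lists passed camera.

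In the sons of ON males, stress and detoxification genes lay lower than in control livers. The unfolded protein response list had a median of -0.24 with 19 of 24 negative, and the chaperone gene Dnajb9 (-0.57 ± 0.14) fell when adjusted over the list alone, with Hyou1 at -0.61 ± 0.21. Asns of the same list lay higher, at 0.89 ± 0.34. The NRF2 list (14 of 18 negative, median -0.21) held the glutathione transferase Gstm2 (-0.76 ± 0.19), and the heat shock list (13 of 17 negative, median -0.17) the co-chaperone Bag3 (-0.52 ± 0.11). Both genes fell when adjusted over their list alone, and Nqo1 and Hspb8 stood at -0.34 ± 0.12 and -0.34 ± 0.14. Xenobiotic metabolism genes had a median of -0.25 with 18 of 22 negative, including Cyp2c38 at -0.77 ± 0.29 and Cyp2c37 at -0.54 ± 0.22.

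Some lipid lists also lay lower in ON F2, though not all of them in each pool, while LXR genes and lipoprotein genes had medians of 0.01 and 0.02. Lipogenesis genes had a median of -0.21 with 20 of 23 negative, beside -0.40 in IUGR F2, including Scd2 at -0.58 ± 0.23, Slc25a1 at -0.24 ± 0.10, Fasn at -0.44 ± 0.31 and Elovl6 at -0.71 ± 0.39. The difference between the F2 groups did not pass for any lipogenesis gene. Cholesterol synthesis genes (17 of 19 negative, median -0.21) included Mvd at -0.62 ± 0.17 and Lss at -0.51 ± 0.21. PPARA targets, the genes of fat oxidation (24 of 28 negative, median -0.11), included Fgf21 at -0.92 ± 0.28 and Hadha at -0.28 ± 0.09. Lipid droplet genes (14 of 18 negative, median -0.18) included G0s2 at -0.77 ± 0.27 and Pparg at -0.62 ± 0.22. Mitochondrial respiratory chain genes (42 of 50 negative, median -0.08) included Ndufs4 at -0.27 ± 0.08 and Cox7a2 at -0.19 ± 0.08. The list medians of pools 13, 14 and 15 were -0.36, -0.24 and 0.02 for lipogenesis and -0.22, -0.22 and 0.01 for lipid droplet genes. They were -0.21, -0.10 and -0.02 for PPARA targets and -0.15, -0.11 and 0.02 for the respiratory chain. For cholesterol synthesis they were -0.09, -0.08 and -0.53. Other splits of these ON F2 and control pools gave medians up to 0.31, 0.22, 0.16, 0.11 and 0.32 in size, in that order. Male-biased genes (13 of 15 positive, median 0.16) included Moxd1 at 1.56 ± 0.75 and Nudt7 at 0.17 ± 0.09, the latter with 1 of 4 probe sets opposite. Cell cycle genes (22 of 29 positive, median 0.11) included Mcm5 at 0.67 ± 0.25, with Pcna at -0.26 ± 0.09. The cell cycle median was 0.24, 0.06 and -0.03 in pools 13, 14 and 15. Pancreas genes (11 of 11 positive, median 1.51), among them the digestive proteases Prss2 at 1.66 ± 0.70 and Ctrb1 at 1.88 ± 0.84, were high in pool 13, whose list median was 4.25 against 0.12 in pools 14 and 15.

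Limma called 0 of 18193 genes between ON F2 and control, with 2755 at an unadjusted p under 0.05 (1071 higher, 1684 lower). All 10 genes named by smallest p shared an adjusted p of 0.0819. These were Steap2, Mmd2 (0.83 ± 0.14), Plch1, Zkscan5 and Kcp on the higher side and Nfxl1 (-0.76 ± 0.12), Rala (-0.56 ± 0.10), Tcof1 (-0.51 ± 0.08), Dnttip2 and Baiap2l1 on the lower side. Among genes above the median level 29 passed. Camera at the preset correlation passed 12 of 43 lists. The adjusted p was 0.000173 for pancreas genes, 0.0136 for the respiratory chain, 0.015 for cholesterol synthesis and the unfolded protein response and 0.0274 for lipogenesis and PPARA targets. It was 0.0304 for NRF2, cell cycle and lipid droplet genes and 0.0442 for the xenobiotic, male-biased and heat shock lists. None held with an estimated correlation (adjusted p = 0.73 with an estimated correlation for each), and 3 passed camera without pool 13. Fry passed 0 of 43 lists.

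The generations of each lineage were then set against each other, without control arrays. In the model without a covariate, ON F2 against ON F1 had the most called genes of the 8 comparisons: 88 genes rose and 173 fell at an adjusted p under 0.05, and 30 of the 261 changed at least 2-fold. They included the sex-dependent genes Moxd1 and Cyp2b9, neither of which passed in ON F1 or in ON F2 against control. Moxd1 rose by 5.17 ± 0.75 (adjusted p = 0.00946), from 6.32 ± 2.00 to 11.49 ± 0.14, and Cyp2b9 fell by 3.04 (SE 0.49, adjusted p = 0.0167), from 7.72 ± 0.92 to 4.68 ± 0.47. In the male-biased list 1 of 15 members rose over all genes and 9 when adjusted over the list alone, with a median of 0.36. In the female-biased list 2 of 15 fell over all genes and 5 over the list alone, with a median of -0.18 and Fmo1 at -0.58 ± 0.10.

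Several genes of metabolism were among those called, while the list medians of gluconeogenesis, LXR, lipoprotein and cholesterol synthesis genes were -0.02, -0.04, -0.01 and 0.07. Pck1, the first enzyme of gluconeogenesis, rose by 1.64 ± 0.38, lipoprotein lipase Lpl by 1.57 ± 0.24, Asns by 1.94 ± 0.34 and the bile acid and sterol pumps Abcb11 and Abcg8 by 0.57 ± 0.13 each. The detoxifying cytochromes Cyp2b10 and Cyp2c38 fell by 2.15 and 1.33, and 9 of 22 xenobiotic metabolism genes fell when adjusted over the list alone (3 over all genes, median -0.28). The lipid droplet coat genes Plin2 and Plin5 fell by 0.57 and 0.64 and the acyltransferase Mogat1 by 1.22. Over their list alone 7 of 18 lipid droplet genes fell and 1 rose (3 and 1 over all genes, median -0.23). Among PPARA targets 11 of 28 fell over the list alone, 2 of them over all genes (Plin2 and Vnn1 at -1.19 ± 0.27, list median -0.19). Gstm2, Abcc3, Sox9 and Bag3 fell by 0.99, 0.97, 0.83 and 0.66, and the imprinted gene Impact rose by 0.36, though 1 of its 3 probe sets pointed the opposite way. Aqp4, a water channel, fell by 2.46, Rec114 by 2.21 and the clock gene Npas2 by 2.19. Aqp4 stood at -0.92 with the mean of its probe sets, and Npas2 at -0.94 with the clock score as a covariate, no longer past the threshold. Ptgds, Tff3 and Camk2b rose by 1.85, 1.80 and 1.68.

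**Figure D3:**
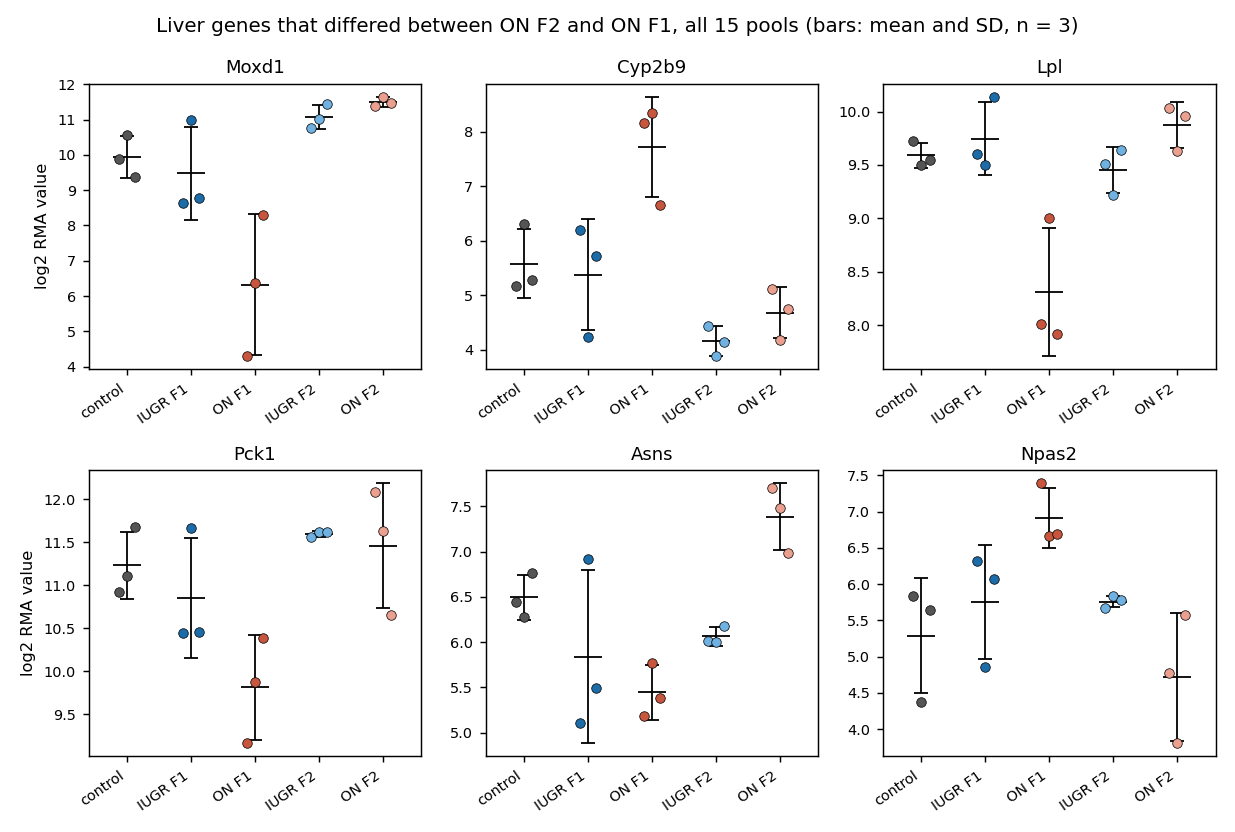
Log2 RMA values of 6 genes called between ON F2 and ON F1 in each of the 15 pools, with bars for the mean and SD of the 3 pools of a group. Moxd1 averaged 6.32 in ON F1 and 11.49 in ON F2, and Cyp2b9 7.72 and 4.68.

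The generations of the ON lineage also differed in clock phase, with clock scores of -3.26, -2.80 and -1.97 in ON F1 and of 3.41, 5.73 and -1.04 in ON F2. With the clock score as a covariate 2 genes were called, fewer than the 3 of IUGR F2 against IUGR F1 and the 4 of IUGR F2 against ON F2 in that fit. The count was 19 without ON F1 pool 7, 26 without ON F2 pool 14, 34 without ON F2 pool 13, 48 without pools 5, 8 and 13 together and 7 when the 6 arrays were fitted alone. Camera passed 13 of 43 lists at the preset correlation, led by male-biased genes (adjusted p = 2.4e-06), and fry passed 3, the male-biased, female-biased and cholangiocyte lists (adjusted p = 0.0114, 0.0434 and 0.0434). None of the 13 held in camera with an estimated correlation, the lowest being adjusted p = 0.136 with an estimated correlation for male-biased genes. The interferon list (23 of 25 negative, median -0.61) and the pancreas list (11 of 11 positive, median 1.33) moved with pools 8 and 13. Without pool 13, 5 lists passed camera, and without ON F1 pool 9, 21.

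In the IUGR lineage, 2 genes rose and 0 fell between F1 and F2. The mitochondrial translation factor Mtif2 rose by 0.64 ± 0.09 and Adi1, an enzyme of methionine salvage, by 0.81 ± 0.11, both at an adjusted p of 0.037. Sppl2a (0.53 ± 0.08) and Slc7a4 (-0.51 ± 0.08) followed at an adjusted p of 0.0524, then Pls1 (-0.93 ± 0.15), Rimklb and Slc15a2. Lipogenesis genes lay lower in IUGR F2 than in IUGR F1 (22 of 23 negative, median -0.38, camera adjusted p = 5.81e-06, and adjusted p = 0.633 with an estimated correlation). Interferon genes lay higher (24 of 25 positive, median 0.37, camera adjusted p = 8.4e-06) and sinusoidal endothelial markers lower (16 of 16 negative, median -0.26, camera adjusted p = 8.75e-05). Their adjusted p was 0.645 and 0.633 with an estimated correlation. In all 12 lists passed camera, 7 without IUGR F1 pool 6 and 0 with an estimated correlation (smallest adjusted p = 0.633 with an estimated correlation). Limma called 0 genes without IUGR F1 pool 4 or without pools 5, 8 and 13 together, and 4 without control pool 3, with 2080 at an unadjusted p under 0.05 in the fit of all arrays.

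The 2 exposures were compared within each generation. In F1, Adi1 was lower in IUGR than in ON livers (8.29 ± 0.10 against 9.15 ± 0.04, adjusted p = 0.0374), and the histone gene H2bc21 was higher (6.45 ± 0.12 against 5.62 ± 0.20, adjusted p = 0.044). Lpl (1.44 ± 0.24) and Camk2b (1.58 ± 0.27) followed at an adjusted p of 0.115. In F2, Mmd2 was lower in IUGR than in ON livers (5.43 ± 0.17 against 6.62 ± 0.23, adjusted p = 0.00788), and Steap2 (-1.57 ± 0.24), Zkscan5, complement C1s1 (-1.01 ± 0.16), Adi1 (0.75 ± 0.11) and Mtif2 (0.56 ± 0.09) followed at an adjusted p of 0.053. Another probe set of Adi1 pointed the opposite way in that comparison. The F1 count of 2 genes was 0 without control pool 3 and 3 without ON F1 pool 9, and the F2 count of 1 was 0 without IUGR F2 pool 11 and 7 without ON F2 pool 14. Camera passed 7 lists in F1 (18 without ON F1 pool 9 and 5 without pool 8) and 9 in F2 at the preset correlation. In F1 interferon genes (median -0.52, or -0.25 without ON F1 pool 8, adjusted p = 2e-13) and in F2 Kupffer cell markers (median -0.35, adjusted p = 8.88e-06) led, and 0 lists held with an estimated correlation (adjusted p = 0.574 and 0.671 with an estimated correlation for those lists).

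The recurrence of a pattern from father to son was examined through genes called in both generations and through the correlation of fold changes across genes. In the IUGR lineage 0 genes were called in the same direction in both generations against control, and in the ON lineage 0. Of genes at an unadjusted p under 0.05, 113 were higher and 94 lower in both IUGR generations, and 320 and 276 in both ON generations. Independent lists of those lengths would share 24.9 and 24.5 genes in the IUGR lineage and 96.1 and 84.7 in the ON lineage. In 100 simulated data sets with unchanged groups and a shared control, 2 groups had a median of 53 and 57.5 such genes in common, and at most 360 and 369. Part of the overlap may come from the shared control pools, and a fit with separate control pools for each generation was not run.

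Fold changes against control correlated across genes with r = 0.38 between IUGR F1 and IUGR F2 and r = 0.27 between ON F1 and ON F2. The ON value was 0.12 without ON F2 pool 15 and 0.41 without control pool 2. Across lineages r was 0.41 for IUGR F1 with ON F2 and 0.26 for ON F1 with IUGR F2. Within a generation r was 0.61 for the F1 groups and 0.49 for the F2 groups. Simulated unchanged groups with a shared control gave a mean r of 0.49, between 0.04 and 0.80 once 2.5% of the simulations were left out at each end. The covariance was 0.0089 in the IUGR lineage and 0.0096 in the ON lineage, beside 0.0102 in the simulation. A comparison with no array in common, IUGR minus ON in F1 against IUGR minus ON in F2, gave r = -0.03 across 18193 genes. Of 100 exact relabellings of the pools 82 gave a correlation at least as large in size (two-sided exact p = 0.82, where the smallest possible p is 0.01). Subtracting ON from IUGR removes any pattern that both lineages share, so this r covers only differences between the lineages. In F1 that difference was small. Limma called 2 genes, and the pools of the groups did not overlap for 9.9% of genes, where chance gives 10%. An r near 0 was therefore likely in advance and cannot decide on recurrence within a lineage. Genes are not independent replicates, and these correlations are across genes.

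**Figure D4:**
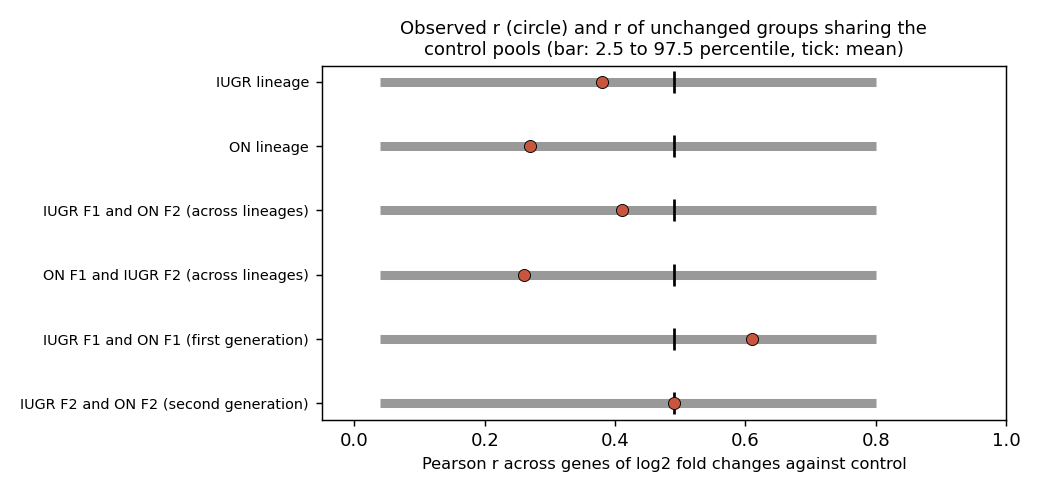
Circles give the Pearson correlation across 18193 genes of the fold changes against control of 2 groups, and grey bars with ticks the range (2.5% left out at each end) and mean of simulations in which neither group differed from control but both shared the same control. The observed correlations of 0.26 to 0.61 lie inside the simulated range of 0.04 to 0.80.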

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

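The tests of a single pool (pool 8), of high control pools and of a longer fast, and the clock score as a covariate, were chosen only after the results were seen.

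The difference between the lineages differed between the generations for 2 genes, by a test of the interaction itself in limma. Mmd2, a membrane protein of the progestin and adiponectin receptor family, had an interaction of -1.78 ± 0.20 (adjusted p = 0.00191), with means of 5.92 in IUGR F1, 5.32 in ON F1, 5.43 in IUGR F2 and 6.62 in ON F2. Adi1, of the methionine salvage pathway, had an interaction of 1.61 ± 0.16 (adjusted p = 0.0011), with means of 8.29, 9.15, 9.10 and 8.34 in the same order. In 100 random splits of the 12 arrays 2 gave as many genes, the real one included. Such splits also break the differences between lineages and between generations, so they cannot test an interaction by itself. The highest other split called 536 genes. Why it did so was not tested, and the 2 genes are weak evidence beside it.

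By the same test with camera, 12 of 43 lists differed in this way at the preset correlation. The median interaction was 0.75 for interferon genes (adjusted p = 3.26e-13, and adjusted p = 0.464 with an estimated correlation), -1.29 for pancreas genes (0.00342 and 0.677) and 0.23 for xenobiotic metabolism (0.0192 and 0.677). It was -0.15 for LXR genes (0.0109 and 0.464), -0.20 for male-biased genes (0.0109 and 0.464), -0.11 for imprinted genes (0.0305 and 0.464) and -0.24 for neutrophil and monocyte markers (0.0305 and 0.677). It was -0.20 for sinusoidal endothelial markers (0.033 and 0.677), -0.14 for stellate cell genes (0.0372 and 0.677), -0.11 for cell cycle genes (0.0395 and 0.677), -0.10 for amino acid and urea cycle genes (0.0395 and 0.677) and -0.17 for lipogenesis (0.0493 and 0.79). None of the 12 held with an estimated correlation. The 2 largest leaned on single pools: the pancreas median was 4.25 in ON F2 pool 13 and 0.12 in pools 14 and 15, and the interferon median of ON F1 against control was 0.47, or -0.06 without pool 8.

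Data that named no gene also held a signal. Of 10092 probe sets without a single gene symbol, which the comparisons above do not use, 2 were called between ON F1 and control in limma, both higher, with 1178 at an unadjusted p under 0.05. The other 3 groups had 0 against control. ON F2 against ON F1 had 29 (19 higher), IUGR F1 against ON F1 had 1, and the remaining comparisons had 0.

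The interferon list lay higher in ON F1 than in control pools. Its median was -0.06 without pool 8, so the shift rested on 1 pool of the 3. The macrophage list median of pool 8 stood 0.20 above pools 7 and 9 and the lymphocyte median 0.01, where the interferon median stood 0.95 above them. By the rule set in advance this argued against more of these cells in pool 8. Many lymphocyte markers lay near background, such as Cd3g, Cd2 and Gzma with means of 3.76, 4.01 and 4.09 over all 15 pools. Changes are understated there, so the lymphocyte median cannot exclude more lymphocytes, and the macrophage median did rise. Pool 8 also had high 3' to 5' ratios (actin 2.22, Gapdh 1.43). IUGR F2 pool 12, with 2.28 and 1.45, had an interferon median of -0.01. A part of RNA length was not tested. An infection or another difference between the animals of pool 8 was not tested either and stays open.

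The lipogenesis list lay lower in IUGR F2 than in control pools, and high control pools alone were argued against by a median of -0.38 in IUGR F2 against IUGR F1, which holds no control array. Clock phase as the whole cause was argued against, since the clock-adjusted change was a median of 1.13 times the unadjusted one (quartiles 1.01 and 1.18). A longer fast, which raises PPARA targets and gluconeogenesis, was argued against by a PPARA median of -0.07 (quartiles -0.20 and -0.01), the lower of the 2 list medians. The rule was tightened with the upper quartile after the values were seen, and single genes pointed the other way: G6pc (0.48 ± 0.16), Pck1 (0.37 ± 0.38), Irs2 (0.47 ± 0.27) and Igfbp1 (0.43 ± 0.62), none past the threshold. The 3' to 5' ratios averaged 2.02 (actin) and 1.28 (Gapdh) in IUGR F2 and 1.87 and 1.15 in control pools. They averaged 2.08 and 1.29 in ON F1, where the lipogenesis median was 0.01. Lineage and generation stay open as a biological difference, untested, as do RNA length, feeding state in other respects and litter.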

How the results depend on the processing

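The clock score as a covariate and the removal of pools 5, 8 and 13 together were chosen only after the data were seen. Of the 21 called results of genes named by the rule 0 turned sign under any of 19 alternatives, but 20 lost their call under at least 1. Calls were lost under 14 alternatives for Tff3, 13 each for Arhgef16, Slc7a4 and H2bc21, 11 for Rasl12, 10 for Mtif2 and for Adi1 in each of its 2 comparisons, 8 for Rec114, 7 for Ptgds and 6 each for Npas2 and Cyp2b10. They were lost under 4 each for Asns, Camk2b and Mmd2 (IUGR F2 against ON F2), 3 each for Rimklb and Cyp2b9, 2 for the Mmd2 interaction, 1 each for Moxd1 and Aqp4 and 0 for the Adi1 interaction. The other called list members printed for ON F2 against ON F1 were not recomputed one by one. The 3 correlations were recomputed with other probe set choices, the brighter genes, renewed normalisation, ranks and single pools left out (IUGR 0.34 to 0.52, ON 0.12 to 0.41 and control-free -0.13 to 0.02 in the last), but not with the clock score, array weights or pools 5, 8 and 13 removed. On simulated data with independent genes 66.5% of changes of 0.5 log2 and 97.3% of changes of 1 were recovered, which need not hold for the real data. Where a count below moved, the cause was not tested, except that the set of brighter genes is smaller and the smaller sets hold fewer arrays.

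Without 1 pool at a time (leave-one-out), the gene counts were 0 to 0 for IUGR F1 against control, 0 to 21 for ON F1, 0 to 1 for IUGR F2 and 0 to 1 for ON F2. They were 0 to 4 for IUGR F2 against IUGR F1, 19 to 313 for ON F2 against ON F1, 0 to 3 for IUGR F1 against ON F1, 0 to 7 for IUGR F2 against ON F2, 7 to 40 for the F test and 2 to 4 for the interaction. The camera list counts were 3 to 9 for IUGR F1, 6 to 13 for ON F1, 6 to 12 for IUGR F2 and 3 to 13 for ON F2 against control. They were 7 to 13 for IUGR F2 against IUGR F1, 5 to 21 for ON F2 against ON F1, 5 to 18 for IUGR F1 against ON F1 and 7 to 12 for IUGR F2 against ON F2.

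The 0 genes of IUGR F1 against control became 1 with the mean of probe sets and 2 with the brighter genes, renewed quantile normalisation or array weights. The 4 of ON F1 became 2 with every probe set, 1 with the mean, 0 without cross-hybridising probe sets, 0 with the brighter genes, 9 with trended robust moderation, 2 with array weights, 0 with 6 arrays, 0 with the clock score and 11 without pools 5, 8 and 13. The 0 of IUGR F2 became 1 with the clock score, and the 0 of ON F2 became 29 with the brighter genes. The 2 of IUGR F2 against IUGR F1 became 1 with every probe set, 4 with the brighter genes, 15 with array weights, 1 with 6 arrays and 0 without pools 5, 8 and 13. The 261 of ON F2 against ON F1 became 101 with array weights, 7 with 6 arrays, 2 with the clock score and 48 without pools 5, 8 and 13.

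The 2 of IUGR F1 against ON F1 became 1 without cross-hybridising probe sets, 0 with 6 arrays and 1 with the clock score. The 1 of IUGR F2 against ON F2 became 3 with every probe set, 0 with the mean, 2 without cross-hybridising probe sets, 8 with the brighter genes, 2 with trended robust moderation, 11 with array weights, 0 with 6 arrays, 4 with the clock score and 0 without pools 5, 8 and 13. The 34 of the F test became 14 with every probe set, 9 with the brighter genes, 53 with array weights and 9 with the clock score. The 2 of the interaction became 1 with the mean, 4 with renewed quantile normalisation, 1 with the clock score and 4 without pools 5, 8 and 13. With an estimated correlation the lists passing camera were 0 in each of the 8 comparisons. The 11 lists of ON F1 became 7 with the brighter genes and 6 with the clock score, and the 12 of ON F2 became 5 with the mean, 3 with the brighter genes, 6 with the clock score and 6 without pools 5, 8 and 13. The 13 of ON F2 against ON F1 became 8 with the brighter genes and 5 without pools 5, 8 and 13, and the 7 of IUGR F1 against ON F1 became 4 without them.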

Other observations

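The clock score as a covariate was chosen only after the results were seen.

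Imprinted genes, which are read from 1 parental copy, passed limma's fry for changes of either sign in the first generation, a test against no change in any member. It passed in IUGR F1 (adjusted p = 0.000419, 16 of 23 positive, median 0.09) and in ON F1 (adjusted p = 3.98e-05, 15 of 23 positive, median 0.07), and the adjusted p was 0.755 in IUGR F2 and 0.293 in ON F2. Between the generations it passed the list in the IUGR lineage (adjusted p = 0.021) and the ON lineage (adjusted p = 0.0064). Over all genes 0 members passed against control, and camera with an estimated correlation gave an adjusted p of 0.975 and 0.927 in the F1 groups. In ON F1 the translation regulator Impact (-0.38 ± 0.08) fell when adjusted over the list alone, a gene chosen after its values were seen. The same test passed lymphocyte markers in IUGR F1 (adjusted p = 0.00163), where Jchain and H2-Eb1 fell by 1.09 and 0.90 over the list alone and the T cell genes Cd3d, Cd4 and Cd2 rose by 0.26, 0.34 and 0.29. In ON F1 it passed 5 lists, the others being cholangiocyte markers (adjusted p = 0.000207), female-biased genes and lipid droplet genes (adjusted p = 0.00978 each) and periportal genes (adjusted p = 0.0139). It passed lymphocyte markers alone in IUGR F2 (adjusted p = 0.00875), 0 lists in ON F2, 16 in ON F2 against ON F1 and imprinted genes alone in IUGR F2 against IUGR F1. In the lipid droplet list of ON F1 the lipase genes Lpl and Pnpla2 fell by 1.29 and 0.30 and Cd36, Mogat1 and Plin4 rose by 0.78, 0.87 and 0.24, adjusted over the list alone. These genes were also chosen after their values were seen.

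Other lists did not pass camera in any of the 4 comparisons with control. List medians in IUGR F1, ON F1, IUGR F2 and ON F2 were -0.01, -0.06, -0.05 and 0.00 for gluconeogenesis, 0.03, 0.02, 0.03 and 0.07 for the IGF axis and -0.01, -0.10, 0.01 and -0.01 for bile acid genes. They were 0.00, -0.01, 0.03 and -0.07 for DNA methylation and chromatin enzymes, 0.00, -0.01, -0.07 and -0.07 for one-carbon metabolism and 0.02, 0.05, -0.03 and 0.02 for lipoproteins. They were 0.02, -0.04, -0.03 and 0.02 for amino acid and urea cycle genes, -0.05, -0.19, -0.25 and 0.03 for the circadian clock and -0.01, 0.01, -0.05 and 0.09 for immediate early genes. Among cell markers they were -0.10, -0.13, 0.07 and -0.02 for pericentral and 0.05, 0.03, -0.01 and 0.02 for periportal genes, -0.01, -0.06, 0.00 and 0.02 for hepatocytes and -0.12, -0.09, -0.16 and 0.05 for neutrophils and monocytes. Erythroid markers stood at -0.01, -0.04, -0.02 and 0.07, adipocyte markers at -0.02, -0.04, -0.01 and -0.07 and gallbladder and gut markers at -0.04, 0.06, 0.00 and 0.07.

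The 261 genes called between ON F2 and ON F1 were set against 2 technical explanations. For clock phase at sampling, the clock-adjusted change was a median of 0.90 times the unadjusted one (quartiles 0.78 and 1.01). The median size went from 0.51 (median SE 0.10) to 0.45 (median SE 0.13), and 2 genes stayed called because the error rose and the change became smaller. All 261 kept their sign. For pancreatic tissue in ON F2 pool 13, the change without that pool was a median of 0.98 times the change with it (quartiles 0.92 and 1.05). Both ratios were taken over called genes, which are favoured by a small spread within groups. A gene moved by 1 pool, or by clock phase within a group, is seldom called, so ratios near 1 were likely in advance. They cannot decide on either explanation. A biological difference between the generations, overfed themselves or fathered by overfed males, stays open and untested.

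With 3 pools against 3 there are 10 splits, too few for a share under 0.05. The real gene counts and the highest other were 0 and 0 for IUGR F1 against control (10 splits as large), 4 and 0 for ON F1 (1), 0 and 0 for IUGR F2 (10) and 0 and 1 for ON F2 (10). They were 2 and 0 for IUGR F2 against IUGR F1 (1), 261 and 0 for ON F2 against ON F1 (1), 2 and 0 for IUGR F1 against ON F1 (1) and 1 and 0 for IUGR F2 against ON F2 (1). The camera list counts were 8 and 14 for IUGR F1 (4), 11 and 21 for ON F1 (6), 10 and 13 for IUGR F2 (2) and 12 and 18 for ON F2 (2). They were 12 and 10 for IUGR F2 against IUGR F1 (1), 13 and 29 for ON F2 against ON F1 (6), 7 and 18 for IUGR F1 against ON F1 (10) and 9 and 15 for IUGR F2 against ON F2 (6). For the F test over 5 groups, 1 of 100 random splits called as many as the real 34 genes, the real one included, with 12 in the highest other. For that count in the main fit, a random assignment of arrays was thus excluded at 0.05. Splits were not run for the alternatives. There the count went from 7 without IUGR F1 pool 6 and 9 with the clock score or the brighter genes to 53 with array weights.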
